A study of Mus musculus with 6 samples.

How the data were processed

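The samples were hippocampi of C57BL/6 mice aged 16 weeks, labelled PHF2 t/g or wild type (WT), with 3 libraries per group. Per the labels' protocols, RNA was extracted with Trizol and 3′ end libraries were made with the QuantSeq kit. Such libraries give about 1 tag per transcript, so counts do not scale with transcript length, and a transcript whose 3′ end lies outside the annotated gene is missed. Per the submitters' processing notes, Bowtie2, edgeR and the genome build mm10 were used. Versions, the counting program, the annotation and any filter are not given in the sources used here. The deposited files hold raw counts per gene symbol, 1 file per library, with no normalization. Each has 23282 rows, of which 44 repeat a symbol and were kept as separate rows. Whether the counting used strand is not given, so overlapping and antisense genes cannot be separated. Library totals were 5512171 to 8844718 counts. Intervals from counts and floors of 3 counts cover counting error only.

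Each sample took its group and replicate number from its title. The tests, gene lists, rule for named genes and the alternatives other than those named last were fixed before the data were examined. Genes were kept by filterByExpr, and libraries were scaled by TMM. Genes were tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, robust glmQLFit, glmQLFTest, genotype as the only term), with Benjamini-Hochberg adjustment over 12831 genes and a threshold of 0.05. Phf2 was also tested by an exact two-sided permutation of the 6 libraries. Lists with 3 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over 32 lists. Camera with an estimated correlation and fry stand beside it. Mitochondrially encoded genes were not analysed here. Named genes are Phf2; the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 0 and groups that do not overlap; in each list up to 4 members past the threshold, otherwise the 1 or 2 with the smallest p; and Ntrk2, Bdnf and Creb1. Other genes named in the report (Egr1, Arc, Fos, Npas4, Ttr, the Y-linked genes, Igfbp2, Cldn5, Adora2a, Gabra3, Ramp3 and Hdc) and all others in the closing section were chosen after their values were seen.

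Coordinates come from RefSeq annotation of GRCm38.p6, to which 23119 of 23238 distinct symbols were matched by name. GC content was taken over the last 500 bases of GENCODE M21 transcripts.

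The depth and composition of the libraries were compared. The ribosomal RNA row Rn45s took 9.26% ± 0.924 of counts in WT and 7.32% ± 0.281 in PHF2 t/g (SD, n = 3). Lrrc17 and Akap5 took 3.41% ± 0.31 and 3.07% ± 0.277 of WT counts, at a ratio of 1.11 to 1.13 in every library, so these rows are uncertain. The biological coefficient of variation was 13.6% in WT and 7.37% in PHF2 t/g. WT replicate 2 stood apart on the first axis of a multidimensional scaling plot (1.08, against −0.533 to 0.152 for the other 5), and PHF2 t/g replicate 1 in its Ttr count. No pair of libraries agreed within sampling noise, the closest pair having a chi-square of 2.96 per gene. The procedure was tested on simulated data with 200 changed genes among 12831 in 20 runs: it recovered 31.5% of genes changed by a log2 of 0.5, 82.2% at 1 and 98.9% at 2, and 7.51% of calls were false. A list shifted by −0.35 was called in 20 of 20 runs and an unshifted list in 0, by an unadjusted camera p under 0.05. Genes were simulated independently of each other. These runs therefore do not measure false list calls where the members of a list are correlated.

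Alternatives were DESeq2's size factors or library size alone in edgeR, DESeq2 1.42.0, limma-voom, no low-count filter, a CPM of at least 1 in 3 libraries, a fit that was not robust, the replicate number as a block, each library left out in turn, an adjusted p threshold of 0.10, and an unadjusted p under 0.05 with 1.5-fold. With DESeq2, lists were tested with limma's cameraPR at the preset correlation on its Wald statistics. All genes with a count entered there, so list members below the low-count filter were included. Chosen after seeing the data were a fit without Rn45s, Lrrc17 and Akap5, a GC correction, a correction for the length of the gene in the genome, and a fit without WT replicate 2 and PHF2 t/g replicate 1.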

Results

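Messenger RNA was profiled by 3′ end sequencing (QuantSeq, which reads 1 tag near the 3′ end of each transcript) in the hippocampus of C57BL/6 mice aged 16 weeks. The study compared animals labelled PHF2 t/g with wild-type (WT) animals, in 3 libraries per group. PHF2 is a Jumonji-domain demethylase of histone H3 lysine 9, and the label is read here as a Phf2 transgene. The comparison asks how hippocampal mRNA differs between these genotypes. The libraries held 5512171 to 8844718 counts each, 6053363 to 8612720 in PHF2 t/g and 5512171 to 8844718 in WT, and 12831 genes passed the low-count filter. Levels are CPM (counts scaled to the library total by TMM), as mean ± SD over n = 3 libraries per group. The labels give separate samples but not separate animals, so the p-values measure the spread between these libraries.

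Phf2 itself (chromosome 13, 48801750 to 48870885, GRCm38) was measured at 38.7 ± 3.96 CPM in PHF2 t/g and 37.7 ± 1.92 CPM in WT. Its log2 fold change was 0.033 (SE 0.114; edgeR adjusted p = 0.929), with a 95% interval of −0.28 to 0.35. The exact two-sided permutation test gave p = 0.9, where 3 against 3 libraries allow no p under 0.1. The construct is not given in the sources used here, and a transgene that lacks the endogenous 3′ end would not be read by these tags, so this value does not check the labels. All 6 libraries held counts of the Y-linked genes Ddx3y (81.5 ± 2.83 CPM in PHF2 t/g, 86.7 ± 4.95 in WT), Uty, Kdm5d and Eif2s3y, none of which passed the test.

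In the hippocampus of PHF2 t/g mice 12 of 27 tested immediate early genes, which neurons transcribe within minutes of activity, fell and 15 did not pass, with 7 past the test with library size alone and 4 to 14 with 1 library left out; the list was lower by camera with a preset correlation (adjusted p = 0.331 with an estimated correlation). Egr4 fell from 338 ± 41.3 CPM in WT to 183 ± 4.77, Nr4a2 from 481 ± 26.8 to 302 ± 30.6, and Egr2 from 21.1 ± 4.77 to 9.37 ± 0.94. Cholesterol synthesis, ribosomal protein and myelin lists were lower by smaller amounts, with 2 of 18, 1 of 44 and 2 of 20 genes past the test. These calls did not hold with an estimated correlation either (adjusted p = 0.207, 0.435 and 0.435). Relative to all genes the myelin median was −0.119 with TMM and −0.118 with library size alone, where its own value was 0.00301. The relative value does not check the scaling, since a change of scaling shifts nearly all genes alike. The hypothalamic peptide hormone genes Avp (vasopressin) and Oxt (oxytocin), close to 0 in WT, were read at 27.3 ± 0.853 and 16.1 ± 1.86 CPM in PHF2 t/g. Marker lists of the striatum, of the meninges and of blood vessels were higher with the preset correlation, with 3 of 11, 1 of 13 and 2 of 19 genes past the test, but not with an estimated one (adjusted p = 0.454, 0.435 and 0.506). Among them Mgp, an inhibitor of calcification, rose from 43.6 ± 8.05 to 112 ± 7.26 CPM. The chemokine gene Ccl21b, at 6.67 ± 0.67 CPM in WT, had 0 counts in the 3 PHF2 t/g libraries.

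**Figure D1:**
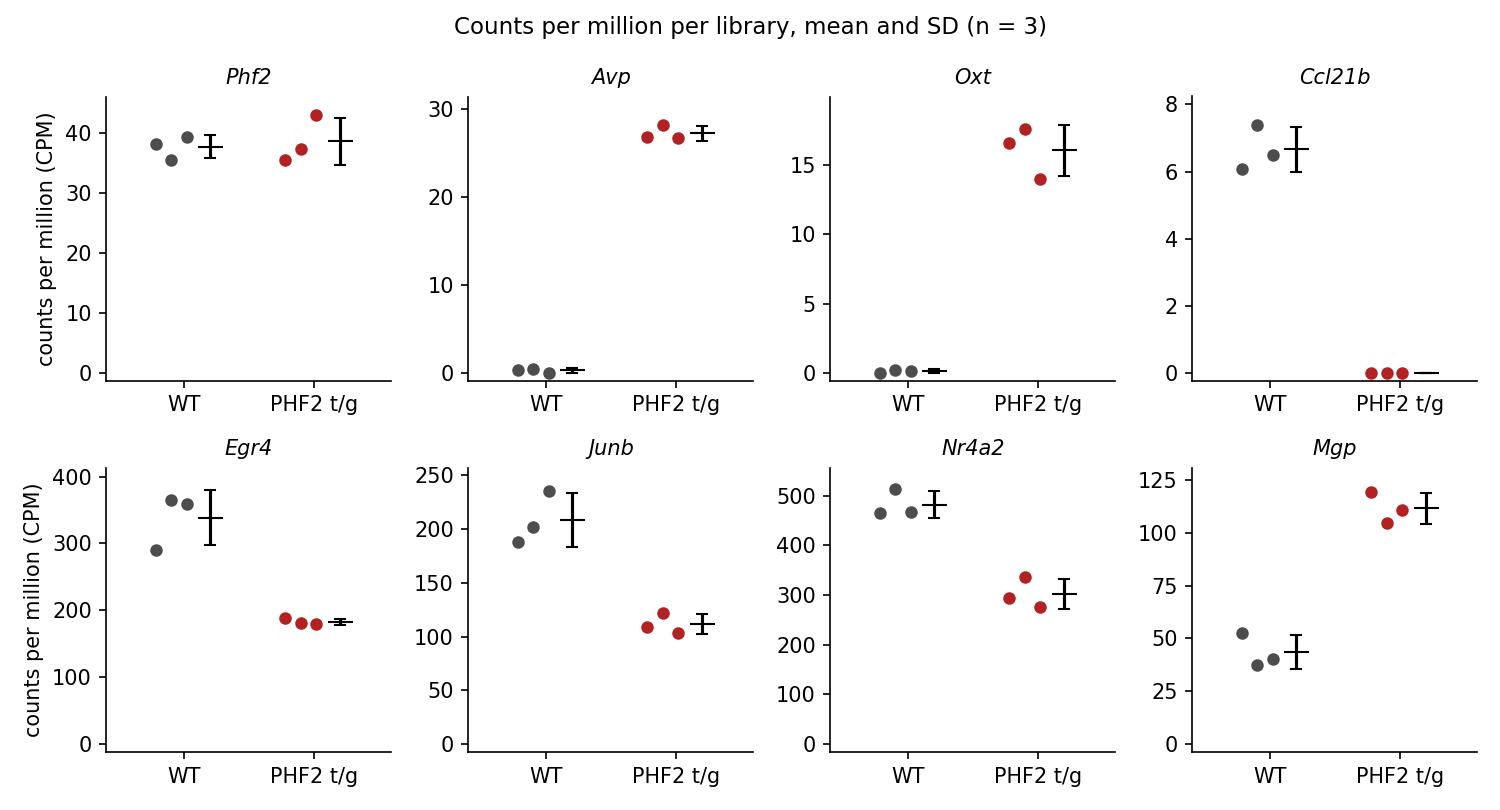
Level of 8 genes in each library, in CPM on linear axes that include 0; points are libraries, and the bar with whiskers is the mean ± SD of 3 libraries (WT grey, PHF2 t/g red). Phf2 overlaps between the groups, whereas Avp, Oxt and Mgp are higher and Ccl21b, Egr4, Junb and Nr4a2 lower in each PHF2 t/g library than in each WT library.

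By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 291 of 12831 genes changed, 100 higher and 191 lower in PHF2 t/g, and 1882 had an unadjusted p under 0.05. In each of the 291 genes the groups did not overlap, as in 20.6% of all tested genes, where chance gives 10%. Most changes were small: 165 of the 291 were under 1.5-fold, and 30 of the higher and 14 of the lower genes reached 2-fold. The submitters' design text gives 119 genes up and 56 down, with no criteria. Without PHF2 t/g replicate 1, 2 or 3 the count was 49, 106 or 116, and it was 162 by limma-voom, 149 without the robust fit and 606 without the low-count filter. The split was 34.4% higher with TMM, 18.5% with DESeq2 (50 higher, 220 lower, with an adjusted p for only 6234 genes) and 74.7% with library size alone (207 higher, 70 lower), where the median log2 fold change of all genes was 0.12 against 0.02.

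Among the genes higher in PHF2 t/g that were named by the rule, Oxt and Avp (chromosome 2, 130574519 to 130577054 and 130580620 to 130582588) had the largest fold changes. Oxt had 360 counts over the PHF2 t/g libraries and 3 over WT, a ratio of 110 with a 95% counting interval of 37.3 to 535. Avp had 607 and 6 counts, a ratio of 92.6 (42.3 to 253), and both passed the test (edgeR adjusted p = 3.74e-09 for Oxt and 3.54e-10 for Avp). These intervals cover counting error only. The hormone precursor gene Trh, from the hypothalamus among other regions, rose 4.05-fold to 6.43 ± 1.68 CPM, and Irs4, an insulin receptor substrate, rose 4.41-fold to 2.87 ± 0.03 CPM. In a hypothalamus marker list chosen after Avp and Oxt were seen, 17 of 35 members passed the low-count filter. Of these 17 tested members 4 rose, 0 fell, and 12 lay above 0 (median log2 fold change 0.36). When adjusted over the list alone 6 were higher and Hdc lower. Angptl4, an inhibitor of lipoprotein lipase, rose 4.63-fold to 5.33 ± 1.21 CPM (edgeR adjusted p = 0.0017), and Vwf, the von Willebrand factor of endothelium, 4.61-fold to 4.35 ± 1.08 CPM. Scgb3a1, Micalcl, Spx, Lrg1 and Tubd1 rose 3.75- to 6.41-fold, each under 5 CPM in both groups. The pseudogene Pisd-ps2 rose 6.49-fold to 4.86 ± 0.989 CPM, which is uncertain because near-identical Pisd copies share its sequence. Oxt, Avp, Pisd-ps2 and Angptl4 kept their calls without each library in turn. Vwf, Lrg1 and Trh lost theirs without PHF2 t/g replicate 1, and Scgb3a1, Micalcl, Irs4, Spx and Tubd1 without any 1 of the 3 PHF2 t/g libraries. Leaving out WT replicate 1 also ended the calls of Scgb3a1, Micalcl, Spx and Tubd1, WT replicate 2 that of Micalcl, and WT replicate 3 those of Scgb3a1 and Tubd1.

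Among the lower genes, Ccl21b (chromosome 4, 42173120 to 42256825) was at least 50.3-fold lower, against a floor of 3 counts over the PHF2 t/g group (edgeR adjusted p = 2.5e-06). Gm3893 (12.3-fold) and Fam205a2 (3.41-fold), from the same part of chromosome 4, also fell; this part holds near-identical copies, so the gene to which the tags belong is uncertain. Galnt9, a brain N-acetylgalactosaminyltransferase, fell from 47.5 ± 7.59 to 17.5 ± 1.42 CPM (edgeR adjusted p = 4.06e-06). Opalin, a membrane protein of oligodendrocytes, fell 2.75-fold to 4.62 ± 1.41 CPM, and Spred2, an inhibitor of Ras-ERK signalling, fell 2.2-fold to 8.86 ± 0.298 CPM. Glp2r fell 2.29-fold and Pcdh1 2.16-fold; both calls ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 3, and with library size alone, and that of Glp2r also without WT replicate 2. Xist fell 4.31-fold to 0.424 ± 0.211 CPM from 2.02 ± 0.588 CPM, a low level in libraries that all express Y-linked genes, and its call ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 1. The small nucleolar RNAs Snora30 (3.15-fold) and Snord89 (2.37-fold) fell as well, although their tags can come from overlapping host genes. The call of Fam205a2 ended without PHF2 t/g replicate 1 or 3 and that of Snora30 without PHF2 t/g replicate 1.

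Of 32 gene lists fixed before the data were examined, 7 changed by camera with a preset correlation of 0.01, 3 higher and 4 lower. None of the 7 calls held with an estimated correlation, and fry, a test of movement on balance in 1 direction, called 1 list, cholesterol biosynthesis (fry adjusted p = 0.00645). The estimated correlation was below the preset 0.01 for the cholesterol (−0.0439) and oligodendrocyte (−0.0253) lists, so correlated members did not end those calls. For the other called lists it was 0.0746 to 0.353. In the immediate early genes, 12 of 27 tested members fell, 0 rose and 15 did not pass; 14 fell when adjusted over the list alone. The 12 became 7 with library size alone, 8 by limma-voom or without the robust fit, 4, 6 or 7 without PHF2 t/g replicate 1, 2 or 3, 8 without WT replicate 3, and 11 without both WT replicate 2 and PHF2 t/g replicate 1. All 27 lay below 0 with TMM or DESeq2's size factors, 22 with library size alone, 23 by limma-voom and 22 to 27 with 1 library left out; the median log2 fold change was −0.34 with TMM (camera adjusted p = 1.11e-10; adjusted p = 0.331 with an estimated correlation). Relative to the median of all genes it was −0.357 with TMM and −0.359 with library size alone. A change of scaling shifts nearly all genes alike. For this and the other lists, a median relative to all genes therefore hardly can move and does not check the scaling. Egr4 fell 1.85-fold, Junb 1.87-fold, Nr4a2 1.6-fold and Egr2 2.22-fold, with edgeR adjusted p of 1.01e-05, 2.08e-05, 1.81e-04 and 0.00164. These 4 kept their calls without each library in turn. Egr1 fell from 1062 ± 178 to 698 ± 51.2 CPM and Arc from 47.3 ± 4.38 to 35.2 ± 2.39 CPM; the call of Egr1 ended without PHF2 t/g replicate 1, 2 or 3 (edgeR adjusted p up to 0.0984), and that of Arc also without WT replicate 2 or 3 (up to 0.301), and library size alone ended both (0.0558 and 0.13). In the same PHF2 t/g libraries the striatum (median 0.38) and leptomeningeal markers (0.55) were higher by camera with the preset correlation. The striatum and leptomeningeal calls did not hold with an estimated correlation. The hypothalamus markers (0.36), listed after Avp and Oxt were seen, had a camera p not adjusted over lists (0.000834, and 0.0228 with an estimated correlation). Their value is thus not comparable with those calls. Fos, at 26.4 ± 2.88 CPM against 33.5 ± 14.8, and Npas4, at 4.84 ± 0.759 against 5.63 ± 0.826, did not pass.

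**Figure D2:**
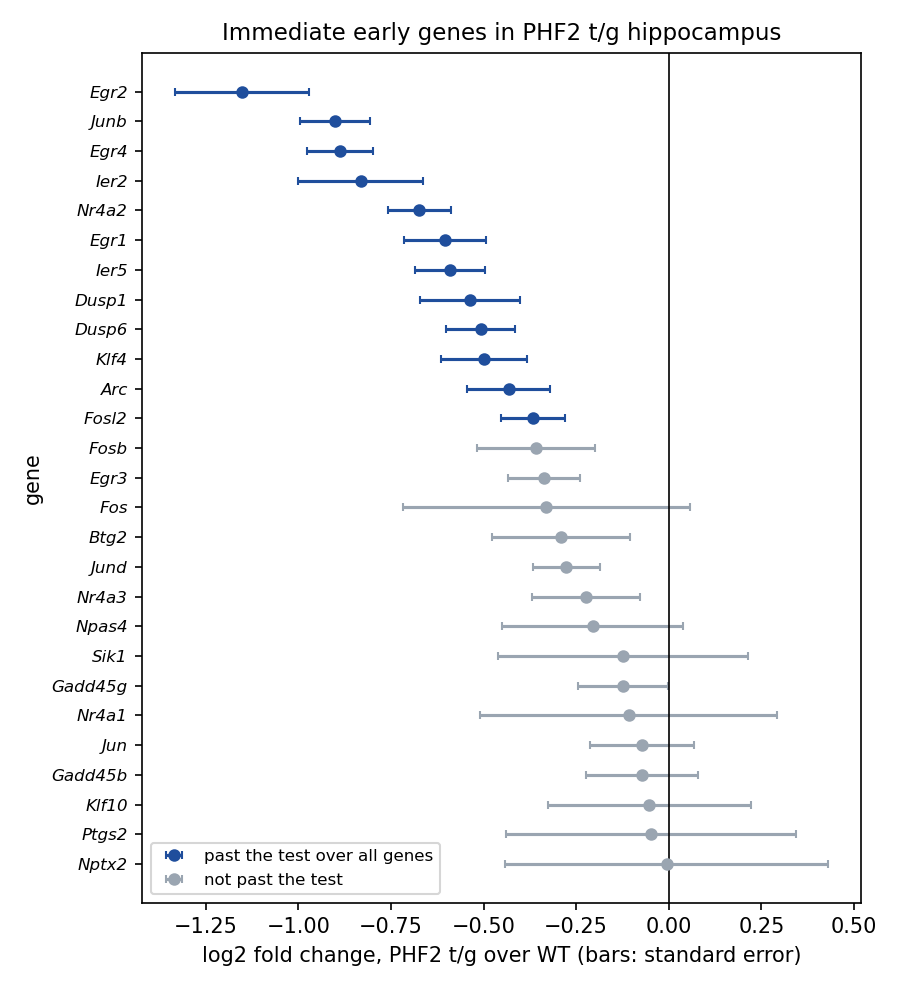
Log2 fold change of PHF2 t/g over WT (horizontal axis) for the 27 tested immediate early genes (rows), with standard errors as bars, from 3 libraries per group scaled by TMM. The 12 genes past edgeR's test over all genes are blue and the other 15 grey, and all 27 points lie below 0 at this scaling, where library size alone leaves 22 below 0 and 7 past the test.

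Of 18 tested cholesterol biosynthesis genes, 2 fell, 0 rose and 16 did not pass, with 5 lower when adjusted over the list alone. All 18 lay below 0 with TMM and 15 with library size alone, with a median relative to all genes of −0.236 and −0.235 (median −0.22 with TMM; camera adjusted p = 2.34e-05; adjusted p = 0.207 with an estimated correlation). Sc5d, a late desaturase of the pathway, fell from 88.5 ± 3.5 to 66.3 ± 0.594 CPM, and Mvd, mevalonate diphosphate decarboxylase, from 77.2 ± 7.34 to 55.5 ± 9.58 CPM. With library size alone 0 passed. Of 44 cytosolic ribosomal protein genes, Rps9 alone fell (1.26-fold, to 776 ± 37.4 CPM), 8 when adjusted over the list alone, with a median of −0.13 (camera adjusted p = 3.22e-04; adjusted p = 0.435 with an estimated correlation); 35 of 44 lay below 0, and with library size alone 0 fell and 23 lay below 0 (median −0.028), while the median relative to all genes was −0.149 with both scalings. Of 20 oligodendrocyte and myelin markers, Opalin and Mag (1.29-fold) fell and 18 did not pass, with 5 lower when adjusted over the list alone. Their median was −0.10 with TMM and 0.00301 with library size alone, or −0.119 and −0.118 relative to all genes (camera adjusted p = 0.0411; adjusted p = 0.435 with an estimated correlation), and the list's call ended without PHF2 t/g replicate 2 (camera adjusted p = 0.0926), WT replicate 1 (0.122) or WT replicate 3 (0.0864), and with library size alone (0.0516). The calls of Sc5d and Rps9 ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 3, that of Mvd without PHF2 t/g replicate 1 or 2 or WT replicate 1 or 3, and that of Mag without any 1 library but WT replicate 3. The list calls of immediate early, cholesterol and ribosomal protein genes held without each library in turn.

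Markers of neighbouring tissues and other cells were among the higher lists. Of 11 striatum markers, 3 rose, 0 fell and 8 did not pass, with 6 higher and Adora2a lower when adjusted over the list alone (median 0.38; camera adjusted p = 3.38e-04; adjusted p = 0.454 with an estimated correlation). The neuropeptide precursor genes Penk, from 142 ± 21.8 to 234 ± 18.5 CPM, and Tac1, from 29.3 ± 2.85 to 49.5 ± 3.21 CPM, rose together with Rgs9 (1.43-fold), a signalling regulator abundant in striatum. The call of Rgs9 ended without any 1 library but WT replicate 2, and those of Penk, Tac1 and Mgp held without each library in turn. Of 13 leptomeningeal and fibroblast markers, Mgp alone rose and 12 did not pass (median 0.55; camera adjusted p = 6.5e-04; adjusted p = 0.435 with an estimated correlation); 9 were higher and Igfbp2 lower when adjusted over the list alone. Of 19 endothelial and mural markers, the VEGF receptor gene Flt1 (1.4-fold, to 56.6 ± 3.4 CPM) and Ly6c1 (1.6-fold, to 15.2 ± 1.23 CPM) rose and 17 did not pass; 3 were higher and Cldn5 lower when adjusted over the list alone. The call of Flt1 ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 3, and that of Ly6c1 also without WT replicate 1. Their list had a median of 0.23 (camera adjusted p = 0.0207; adjusted p = 0.506 with an estimated correlation), and the call ended without PHF2 t/g replicate 3 (camera adjusted p = 0.0675), WT replicate 2 (0.108) or WT replicate 3 (0.174), and with library size alone (0.0587). The choroid plexus list did not change (5 tested members; camera adjusted p = 0.116), although PHF2 t/g replicate 1 held 292 CPM of Ttr, its most abundant transcript, against 1.29 to 4.46 CPM in the other libraries. Clic6 was higher when adjusted over the list alone, at 5.68 to 15.9 CPM in the PHF2 t/g libraries against 2.09 to 3.64 CPM in WT. For Ttr, Prlr and Enpp2 the libraries of the groups overlapped. The median of the list was 1.53, and 0.0801 without PHF2 t/g replicate 1. The list was called without PHF2 t/g replicate 2 (camera adjusted p = 0.0101) or replicate 3 (0.0363). With all libraries it was called without the low-count filter (camera adjusted p = 0.00148) and with DESeq2 (cameraPR adjusted p = 1.24e-08). Both of these also include members below the low-count filter.

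**Figure D3:**
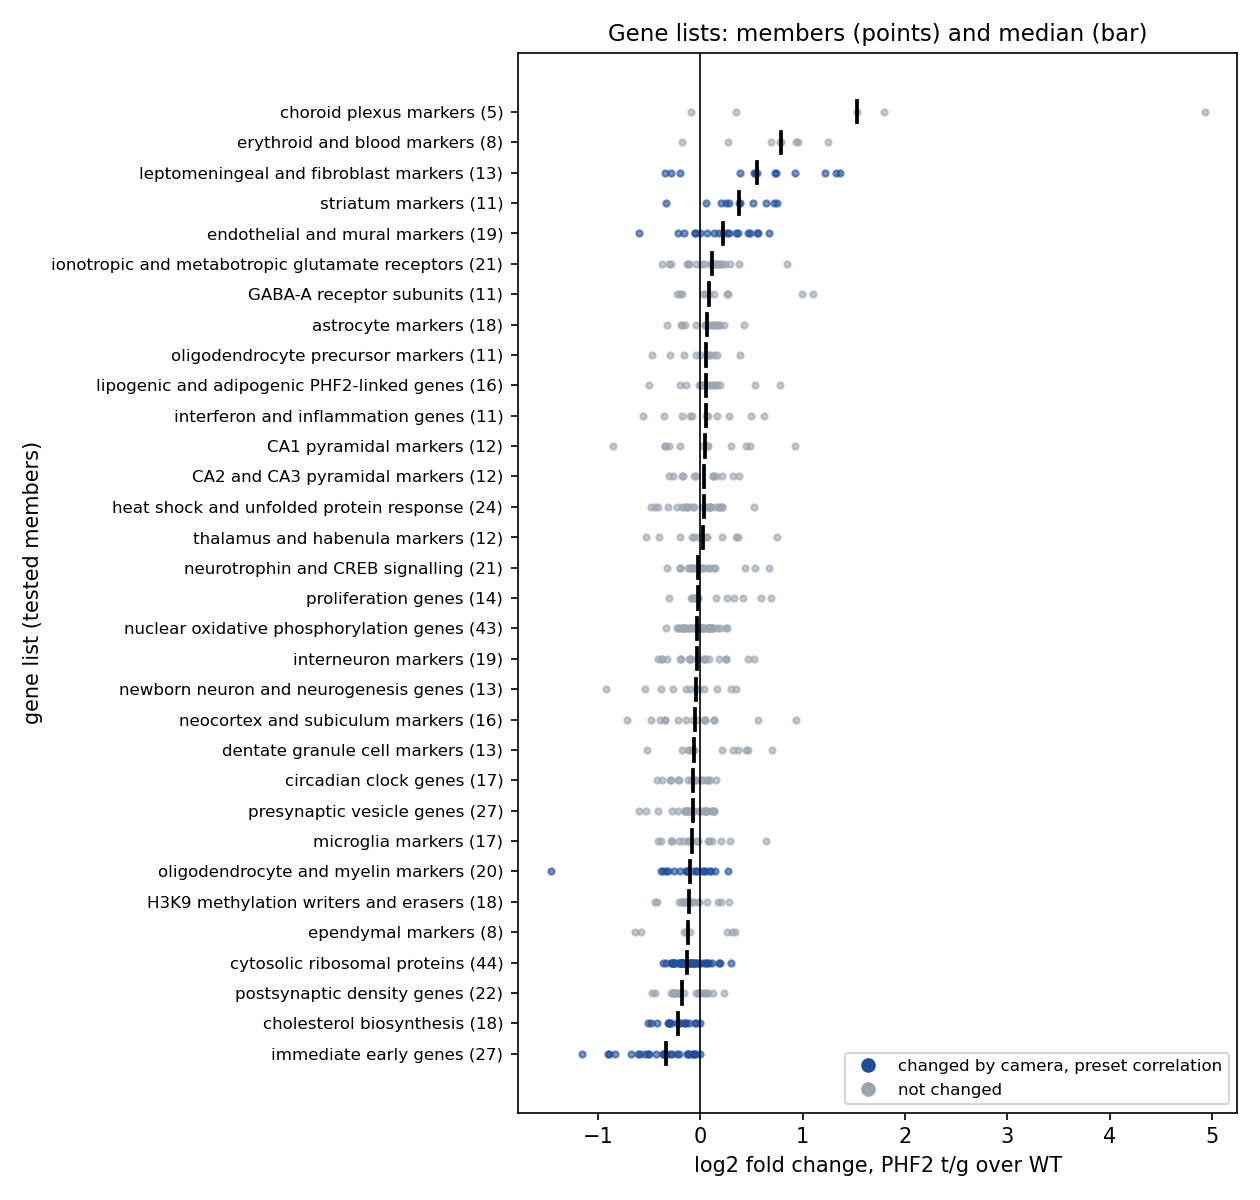
Log2 fold change of PHF2 t/g over WT (horizontal axis, TMM) for the tested members of 32 gene lists (rows, number of tested members in brackets); points are genes and the black bar is the list's median. The 7 lists changed by camera with a preset correlation are blue, with medians from −0.34 (immediate early genes) to 0.55 (leptomeningeal and fibroblast markers), and the others grey.

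The other 25 tested lists did not change (camera adjusted p from 0.058 to 0.981). In the GABA-A receptor list, 2 of 11 members rose. Gabrg1 rose from 15.3 ± 3.43 to 32.2 ± 3.33 CPM and Gabra2 from 8.77 ± 0.654 to 17.4 ± 1.5 CPM (edgeR adjusted p = 5.61e-04 and 0.00198). Gabrg1 and Gabra2 lie close together on chromosome 5 (70751047 to 70842617 and 70958392 to 71095849), so their rises may not be independent. For Gabra2, a difference in mouse substrain between the groups stays open, as described in the closing part. In this list 3 members were higher and Gabra3 lower when adjusted over the list alone. Of 27 presynaptic genes, Stx1a (1.33-fold) and Rims1 (1.44-fold) fell, 3 when adjusted over the list alone. Of 22 postsynaptic density genes none passed over all genes, 4 were lower and 1 higher when adjusted over the list alone, and Camk2a (log2 fold change −0.27) and Nrgn (−0.26) had the smallest p. Of 21 glutamate receptor genes none passed by either adjustment (Gria2 0.21, Grin2b 0.19). Of 13 newborn neuron genes, Sox4 (1.45-fold) and Tubb3 (1.3-fold) fell, and 3 were lower and 1 higher when adjusted over the list alone. Of 19 interneuron markers, Gad2, a GABA-synthesising enzyme, rose 1.44-fold to 82.9 ± 2.9 CPM and Sst, somatostatin, fell 1.31-fold to 116 ± 3.2 CPM, with 2 higher and 3 lower when adjusted over the list alone. Wfs1 (1.4-fold) rose among 12 CA1 markers, Tac1 among 12 thalamus and habenula markers, where Ramp3 was lower when adjusted over the list alone, and Fn1 (1.91-fold) among 16 neocortex and subiculum markers, of which 2 were higher and 4 lower when adjusted over the list alone. Gabrg1, Gabra2 and Fn1 kept their calls without each library in turn. Without PHF2 t/g replicate 1 the calls of Stx1a, Rims1, Sox4, Tubb3, Wfs1, Gad2 and Sst ended. Stx1a lost its call without PHF2 t/g replicate 2 or WT replicate 3 too, Tubb3 without PHF2 t/g replicate 3, Wfs1 and Sst without PHF2 t/g replicate 2 or 3 or WT replicate 3, and Rims1 without any 1 library but WT replicate 2.

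Further lists had 1 or 2 changed members. Among 17 clock genes Nr1d1 fell 1.34-fold, among 43 oxidative phosphorylation genes Cox6c fell 1.26-fold, and among 24 heat shock and unfolded protein response genes the transcription factor genes Atf4 (1.33-fold) and Ddit3 (1.35-fold) fell; 2, 1 and 3 members of these lists were lower when adjusted over the list alone. All 4 calls ended without PHF2 t/g replicate 1. Those of Nr1d1, Cox6c and Ddit3 ended without PHF2 t/g replicate 2, those of Nr1d1 and Cox6c without PHF2 t/g replicate 3, that of Nr1d1 without WT replicate 1 and that of Cox6c without WT replicate 3. Of 21 neurotrophin and CREB signalling genes none passed: Bdnf, a neurotrophin, was at 95.9 ± 6.5 CPM against 120 ± 14.3 (log2 fold change −0.32; edgeR adjusted p = 0.0931, 0.00506 without WT replicate 2, 0.0274 without the low-count filter, 0.0319 with a GC correction, 0.0468 with a gene length correction and 0.0364 without both WT replicate 2 and PHF2 t/g replicate 1), and its receptor gene Ntrk2 (−0.018) and Creb1 (0.015) were near 0. None of 18 tested H3K9 methylation enzymes and readers passed (Suv39h1 −0.42, Kdm3b −0.44; camera adjusted p = 0.206), nor did any of 16 genes of lipid synthesis and storage linked to PHF2 (Acaca 0.54, Pklr 0.78). Over all genes no member passed among 13 dentate granule cell markers (Pdzd2 0.70, Calb1 0.21), 12 CA2 and CA3 markers (Bok −0.26, Dkk3 −0.17), 18 astrocyte markers (Gjb6 0.24, Aqp4 −0.32), 11 oligodendrocyte precursor markers (Olig2 −0.47, Pdgfra 0.38) or 17 microglia markers (Cx3cr1 −0.41, Tmem119 0.64); Pdzd2 was higher and Cx3cr1 lower when adjusted over the list alone. The same held for 8 ependymal (Tekt1 −0.64, Pltp −0.15), 8 blood (S100a8 1.25, Lyz2 0.69), 14 proliferation (Plk1 0.60, Tyms 0.69) and 11 interferon and inflammation genes (Ifit3 −0.35, Nfkb1 0.62). The blood list was called without WT replicate 1 (camera adjusted p = 0.00335) or WT replicate 2 (0.0218), with DESeq2 (0.0139), limma-voom (0.0156), no low-count filter (0.00568), the replicate number as a block (0.00345) or a gene length correction (0.0292), and without both WT replicate 2 and PHF2 t/g replicate 1 (0.0477). The clock list was called without WT replicate 2 (0.00657), PHF2 t/g replicate 2 (0.0223) or both WT replicate 2 and PHF2 t/g replicate 1 (0.0134), with DESeq2 (0.0139) and with a GC (0.0391) or gene length correction (0.0396). DESeq2 also called the GABA-A receptor (0.0307), presynaptic (0.0139), postsynaptic (0.0179) and newborn neuron (0.0179) lists, and the gene length correction the presynaptic list (0.046). The DESeq2 values given for lists are adjusted p of cameraPR. The clock list had a median of −0.070, and 0.031 with library size alone, or −0.09 and −0.0903 relative to all genes. The median, mean or camera direction differed in sign for the neurotrophin, proliferation, dentate, CA1, CA2 and CA3, oligodendrocyte precursor, thalamus, heat shock and interferon lists, whose medians lay between −0.06 and 0.06.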

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

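The GC and gene length corrections, the fit without Rn45s, Lrrc17 and Akap5 and the fit without both libraries that stood apart were chosen after seeing the data. The 291 calls became 606 without the low-count filter (229 higher, 377 lower), 162 with limma-voom (53 and 109), 149 without the robust fit (51 and 98), 140 without both libraries that stood apart (47 and 93), and 547 at an adjusted p under 0.10 (193 and 354). Library size alone gave 207 higher and 70 lower, DESeq2 50 higher among the 6234 genes it gave an adjusted p, and an unadjusted p under 0.05 with 1.5-fold 292 higher. With 1 library left out the count was 49 to 392 (24 to 129 higher, 25 to 263 lower). The filters and left-out libraries change the number of genes or samples tested, and the thresholds change only which genes of the same fit are counted; for the others the cause was not tested. None of the 291 calls changed sign in any of these fits. This does not check the calls: the groups of all 291 did not overlap, so leaving out a library could hardly turn a sign. Of 51 named genes that passed, 20 kept their calls without each library in turn: Oxt, Avp, Pisd-ps2, Angptl4, Ccl21b, Gm3893, Opalin, Galnt9, Snord89, Egr2, Spred2, Egr4, Junb, Nr4a2, Gabrg1, Gabra2, Mgp, Tac1, Fn1 and Penk. These 20 were also past the threshold in every other edgeR and voom fit that tested them, whereas DESeq2 gave no adjusted p to 25 of the 51. Library size alone ended 13 of the 51 calls: Glp2r, Pcdh1, Stx1a, Rims1, Tubb3, Sst, Mag, Nr1d1, Cox6c, Rps9, Ddit3, Sc5d and Mvd. Without PHF2 t/g replicate 1, 2 and 3, calls ended for 31, 22 and 21 of the 51, and without WT replicate 1, 2 and 3 for 11, 3 and 15.

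The 7 list calls became 14 with DESeq2, 10 with the gene length correction, 0 with an estimated correlation and 1 with fry, and 5 to 8 with 1 library left out. The DESeq2 number comes from cameraPR on Wald statistics over all genes with a count. Both the test and the list members thus differ from those of the main fit. The immediate early, leptomeningeal, striatum, ribosomal protein and cholesterol lists held in all 18 refits with the preset correlation; the oligodendrocyte list was lost in 5 and the endothelial list in 6.

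Library size alone moved the median log2 fold change of all genes from 0.02 to 0.12. The median of the oligodendrocyte list was 0.00301 there, and −0.118 relative to all genes (−0.119 with TMM). The relative value does not check the scaling, since a change of scaling shifts nearly all genes alike. The log2 fold changes of named genes and the camera directions of lists turned only for values short of the threshold. The Phf2 log2 fold change was −0.0208 with the GC correction, −0.0141 with the gene length correction and −0.0512 to 0.0924 with 1 library left out. Ntrk2 was 0.0828 with library size alone and −0.0354 to 0.00503 with 1 library left out, and Creb1 −0.0376 with the GC correction, −0.0311 with the gene length correction, −0.109 without both libraries that stood apart and −0.0556 to 0.121 with 1 library left out. For the lists, the direction of camera turned and the median is given, last with 1 library left out. CA1 was 0.038 with DESeq2's size factors, 0.0483 with DESeq2, 0.0627 without the filter, −0.024 with the GC correction, 0.0216 with the gene length correction and −0.134 to 0.112. The dentate list was 0.039 with library size alone, −0.11 without both libraries that stood apart and −0.0829 to 0.2. CA2 and CA3 was 0.0436 with the block and −0.119 to 0.0728. The thalamus list was 0.0806 with DESeq2, 0.00221 with limma-voom, 0.0832 without the filter and −0.106 to 0.147. The interferon list was 0.0581 with DESeq2, 0.0535 with limma-voom, 0.0651 without the filter, 0.122 with the CPM filter, 0.0572 with the block, 0.0485 with the gene length correction and 0.00391 to 0.0777. The ependymal list was −0.239 to 0.206 and the oligodendrocyte precursor list −0.107 to 0.111.

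With the replicate block the count was 299 (101 higher, 198 lower). Deviations of libraries with the same number correlated at −0.00445, 0.123 and 0.0846, against −0.126 to 0.0671 for different numbers. The values of replicates 2 and 3 were thus above all of the latter, though small. The labels give no pairing, so the main fit had no block. The block ended the calls of Glp2r, Pcdh1, Mag and Mvd and of the oligodendrocyte (adjusted p = 0.0508) and endothelial (0.053) lists, and the blood list became called (0.00345). The depth recovered 31.5% of simulated changes of 0.5 log2, so small changes can be missed. Alternatives for normalized values were not run, as the files hold counts.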

Other observations

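The tests of lateral and arcuate hypothalamus, of Avp in a single library, of the summed Ccl21 counts, of chromosomes, of gene length and of hippocampal neuron markers, and the count of hypothalamus markers short of the threshold, were chosen only after the result was seen. The other tests were set before their values were computed, but after the genes with the smallest p had been read and, for the glucocorticoid test, after all changed genes had been read. All genes named in this part were chosen after their values were seen. The SE of a median in this part is taken over the genes of the list. It does not measure the spread between libraries or the correlation between genes.

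Further genes rose in PHF2 t/g with edgeR, and the calls of Dlk1, Cdh1 and Vegfa held without each library in turn. Dlk1, an imprinted gene of the delta-like family, rose from 13.1 ± 2.52 to 41.5 ± 4.67 CPM, and Cdh1, E-cadherin, from 8.61 ± 0.592 to 21.4 ± 0.899 CPM (SD, 3 libraries each). Vegfa, an angiogenic growth factor, rose from 50.3 ± 3.39 to 79.5 ± 2.55 CPM. The nuclear noncoding RNAs Malat1, Meg3, Miat and Kcnq1ot1 rose by log2 fold changes of 0.40, 0.36, 0.34 and 0.46. The calls of all 4 ended without PHF2 t/g replicate 1, and those of Malat1, Meg3 and Miat also without PHF2 t/g replicate 2 or 3 or WT replicate 3. Leaving out WT replicate 1 also ended those of Meg3 and Miat.

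On chromosome 4, 6 of 8 tested genes between 42089373 and 42665763 fell: Gm3893, Gm13306, Ccl21b, Fam205a2, Ccl27b and Il11ra2. In 295 of 10000 random draws of as many genes a run was as long. The draws treat genes as independent, whereas the near-identical copies in this part can share tags. The ends of the span were also set by the genes that fell. The calls of Ccl21b, Gm3893 and Il11ra2 held without each library in turn, whereas Gm13306 lost its call without PHF2 t/g replicate 1 or 2, Fam205a2 without PHF2 t/g replicate 1 or 3, and Ccl27b without PHF2 t/g replicate 1, 2 or 3 or WT replicate 3, and with library size alone (edgeR adjusted p = 0.0575).

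For the count of 291 changed genes, the 6 libraries make 10 splits into 3 and 3, which cannot give a share under 0.05. The real split had 291 genes (1 of 10 splits had as many) and the highest of the others 0.

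Avp and Oxt were near 0 in WT and higher in each PHF2 t/g library, at similar levels across these libraries (Avp 26.7 to 28.3 CPM, Oxt 14 to 17.6 CPM). On chromosome 2, 3 of 15 tested genes between 129686549 and 130582588 rose: Pdyn, Oxt and Avp. The call of Pdyn held without each library in turn. The cause of this run was not tested. A source in a single library is argued against by the lowest log2 fold change of Avp with a PHF2 t/g library left out, 6.43, and tissue from the lateral or arcuate hypothalamus by Pmch, Hcrt, Agrp and Pomc, abundant there, whose highest mean in PHF2 t/g was 1.65 CPM (Pomc, 1.77 in WT). A candidate explanation is tissue from other parts of the hypothalamus. The other markers had a median log2 fold change of 0.361 (SE 0.254, camera p = 0.000834, 0.0228 with an estimated correlation), 12 of 17 tested above 0. However, Hdc (−0.99) was lower when adjusted over the list alone, and Crh, of the same nucleus as Avp and Oxt, was at −0.23. Crh was already at 47.6 ± 2.68 CPM in WT (40.4 ± 4.71 in PHF2 t/g). A small addition of tissue may not show at that level, so Crh decides little. Only 17 of the 35 listed markers passed the low-count filter, which also keeps a gene that is high in 1 group alone. Irs4 entered this way (18 to 26 counts in PHF2 t/g libraries, 1 to 8 in WT), so the median can lean upward. The tested markers include Trh, Six3, Irs4 and Asb4, which rose. The other 13 had a median of 0.325 (SE 0.194, camera p = 0.147, 0.2 with an estimated correlation). These 13 were chosen because they did not pass the test, which by itself weakens their camera p. How far the shift rests on the genes that rose is therefore not settled. Of the 35 markers listed, 16 reach 1 CPM in WT hippocampus and 1, Gal, is in another list. An effect of the genotype on these genes was not tested and stays open; the calls of Trh and Six3 were lost without PHF2 t/g replicate 1, that of Irs4 without PHF2 t/g replicate 1, 2 or 3, and that of Asb4 without any 1 library but WT replicate 3.

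Nnt rose from 9.58 ± 2.39 to 20.7 ± 0.463 CPM and Gabra2 from 8.77 ± 0.654 to 17.4 ± 1.5 CPM, while Ccl21b had 0 counts in PHF2 t/g. Tags moved between near-identical Ccl21 copies are argued against by the sum of these copies, 207 counts in WT and 1 in PHF2 t/g, a ratio of 226 with a 95% counting interval of 40.2 to 8980. A single segment linked to the transgene is argued against by the 3 chromosomes that hold the genes. A difference in C57BL/6 substrain between the groups could give such changes and stays open: 1 of 5 other tested substrain genes, Entpd4, had an unadjusted p under 0.05, which is too few to decide. Wdfy1, which also differs between substrains, rose from 21.2 ± 2.48 to 49.8 ± 2.25 CPM and held without each library, but like the first 3 it was seen before the test was set, and the call of Entpd4 ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 1.

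The immediate early genes had a median log2 fold change of −0.337 (SE 0.0732). A trend with GC content or gene length as the whole cause is argued against by the medians after correction for each, −0.382 (SE 0.0743) and −0.342 (SE 0.0724). Fewer hippocampal neurons are argued against by 36 markers of these neurons, with a median of 0.0462 (SE 0.0745). With 1 library left out, the medians of the separate dentate, CA1 and CA2 and CA3 lists lay between −0.134 and 0.2. That of the immediate early genes lay between −0.452 and −0.237 over all 18 refits. Without Rn45s, Lrrc17 and Akap5 the median was again −0.337, but this decides nothing, since that setting moved the genes by a median of only 0.000171. Handling or the time of tissue collection, a difference in the dissected tissue or in the RNA fraction, and an effect of the genotype on neuronal activity may each lower these genes. They were not tested and stay open. In the same libraries the striatum (median 0.38) and leptomeningeal markers (0.551) were higher by camera with the preset correlation. With an estimated correlation the striatum (camera adjusted p = 0.454) and leptomeningeal (0.435) calls did not hold. The hypothalamus markers (0.361) had only a camera p not adjusted over lists (0.000834, and 0.0228 with an estimated correlation), from a list chosen after Avp and Oxt were seen. The nuclear RNAs Malat1, Meg3, Miat and Kcnq1ot1 were also higher.

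Fkbp5, Angptl4, Apod and Cebpd, which glucocorticoids induce, rose by log2 fold changes of 0.81, 2.21, 0.54 and 0.85. Whether this could reflect glucocorticoids was left undecided by 15 other induced genes, with a median of 0.108 (SE 0.0769), 11 of them above 0 and 0 past the threshold of edgeR. The limma camera p of these genes was 0.0991, and 0.153 with an estimated correlation. The call of Cebpd ended without PHF2 t/g replicate 1, 2 or 3 or WT replicate 3, and those of Fkbp5, Angptl4 and Apod held without each library in turn.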
